A study of Mus musculus with 4 samples.

How the data were processed

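RNA of 4 samples of mouse CD4+ T cells was hybridised to NimbleGen expression arrays with Cy3, 1 array per sample, per the labels' protocols. The labels' growth and treatment protocols describe a bacterial culture and not these cells, so the isolation and stimulation are known only from the sample descriptions, which name splenocytes, magnetic beads and activation for 48 hours. The authors normalized the arrays with RMA (robust multi-array average, version not given), per the submitters' processing notes. The deposited values are a normalized intensity per row on a linear scale: they range from 21.7 to 64873, although a file header calls such values log2 transformed. The authors' deposited comparison tables add a fold change, which is the ratio of the larger to the smaller intensity of both arrays. All 283288 intensities in the 8 comparison tables equal those of the value table within a relative tolerance of 1e-06, and so do the recomputed ratios, so all results here start from the value table. No deposited fold change is quoted. Unnormalized intensities, and the detection calls that would come with them, were not used here.

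The tables name a gene for 33663 of 35411 rows; the other 1748 were left out of gene-level steps. For 31529 rows the gene number matched a reference gene table (GRCm38.p6), which changed 4510 old symbols; 2134 rows kept the symbol of the file. Coordinates are not given because the build behind the array design is not given in the sources used here. Of the 20735 genes, 7950 had several rows, and each was represented by the row with the highest mean over the 4 arrays. Where a gene had several rows above the floor, their log2 differences had a pooled SD of 0.34 in the naive and 0.35 in the genotype comparison of the arrays labelled activated, 0.45 in both activation comparisons and 0.49 in the difference of differences. This SD compares probe sets on the same arrays and is no replicate error.

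Intensities were taken to log2. The floor of an array was the 95th percentile of 666 rows of olfactory, vomeronasal, trace amine and taste receptor genes (618 genes). Values below the floor were set to it, and a difference with 1 side below is a lower bound, printed as "at least", "or more" or "a bound". Where this left no bound (both sides below, or the floor above the measured value) the difference was set to 0, a refinement made after seeing that the floors differ between arrays. Genes above the floor on at least 1 array of a comparison were counted as apart at a log2 difference of 1 or more. In the difference of differences each genotype difference was treated this way first.

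With 1 array per group no test was run. Gene lists, 28 of them fixed before the data were examined and 11 lists of tissue genes written after the genes with the largest differences had been seen, were described by the median of members above the floor. The median was placed among 10000 random lists of the same size matched on mean intensity in 20 bins, as a description of these arrays. A list with at least 5 members above the floor was said to lie outside the limits below percentile 2.5 or above 97.5. Genes are named by a rule fixed beforehand: per comparison, the 10 highest and 10 lowest among genes above the floor on all arrays compared whose rows share a direction, and the 5 largest bounds in each direction, leaving out unnamed transcripts, predicted genes, pseudogenes and antigen receptor segments. Other genes named are list members. Some genes that meet these rules are not reported here.

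Simulated arrays were made from the naive pair, with noise of SD 0.34 and 3210 genes above the floor. The count recovered 94 of 100 genes changed by 1.5 on the log2 scale and 100 of 100 changed by 3. It called 5 of 3010 unchanged genes. That noise was the SD between rows of a gene, which is no replicate error. Measured naive differences of genes above both floors had an SD of 0.45. Changed genes were drawn from the more intense genes above both floors. These rates are therefore not error rates of the counts below. Of 200 unchanged lists of 12 genes 8 lay outside the limits (4%), and a list shifted by 0.5 lay at percentile 100.

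Alternatives fixed beforehand were centring on the median difference, removal of a lowess trend on mean intensity (fraction 0.3), no floor, a floor at the 99th percentile and the mean of all rows of a gene. A floor at the 75th percentile and quantile normalization of each genotype pair alone were added after seeing the data. A comparison from unnormalized intensities and a search for miR-7 seed sites in 3' untranslated regions had been planned and were not run, since unnormalized values and transcript sequences were not used here. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.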

Results

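RNA labelled as that of mouse CD4+ T cells of the FVB/N background was profiled on 4 single-colour microarrays, 1 for each group. The groups were naive cells (CD4+ cells with high CD62L, the lymph node homing receptor) of wild type mice, naive cells of mice labelled deficient in the microRNA miR-7, and cells of both genotypes labelled as activated for 48 hours. The labels call each sample representative of 3 biological replicates, but each group has 1 array here. Every difference below is therefore a difference between 2 arrays with no replicate check, and no p-value is given. The number of arrays, not the number of genes, limits the precision.

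Each array gave a normalized intensity for 35411 rows, which name 20735 genes. Median intensities were 204 for wild type naive, 203 for miR-7 deficient naive, and 201 and 200.2 for the wild type and miR-7 deficient arrays labelled activated. The floor, set from olfactory, vomeronasal and taste receptor genes that lymphocytes are not known to use, lay at 984, 987, 721 and 606 in the same order. Above it stood 2847, 3051, 4603 and 5340 genes. The naive arrays correlated at r = 0.900 across rows (log2 scale) and the arrays labelled activated at 0.923, while arrays labelled naive and arrays labelled activated correlated at 0.723 to 0.750. Rows are not independent replicates.

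The targeted microRNA checks no label here, because none of its 3 loci (Mir7-1, Mir7-2 and Mir7b) had a row. Of the list of miR-7 loci and known miR-7 regulators, the member above the floor was Hnrnpk, the gene whose intron holds one of the loci. Its intensity was 1960 in wild type and 3086 in miR-7 deficient naive cells, and 3858 and 3407 on the arrays labelled activated. The messenger of a host gene does not measure the microRNA.

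The arrays labelled activated carried abundant transcripts of the nervous system and few of T cells. Mbp, the myelin basic protein, read 370 and 241 on the wild type and miR-7 deficient naive arrays and 23744 and 17055 on the arrays labelled activated. Nrgn, a postsynaptic calmodulin-binding protein of neurons, read 92.0 and 126 against 15125 and 22284, and Cd3e, a chain of the T cell receptor complex, read 1680 and 1220 against 419 and 434. Both arrays labelled activated lay below their floor for Cd3e. Every direction drawn from these 2 arrays holds for them and not for a verified cell state.

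**Figure D1:**
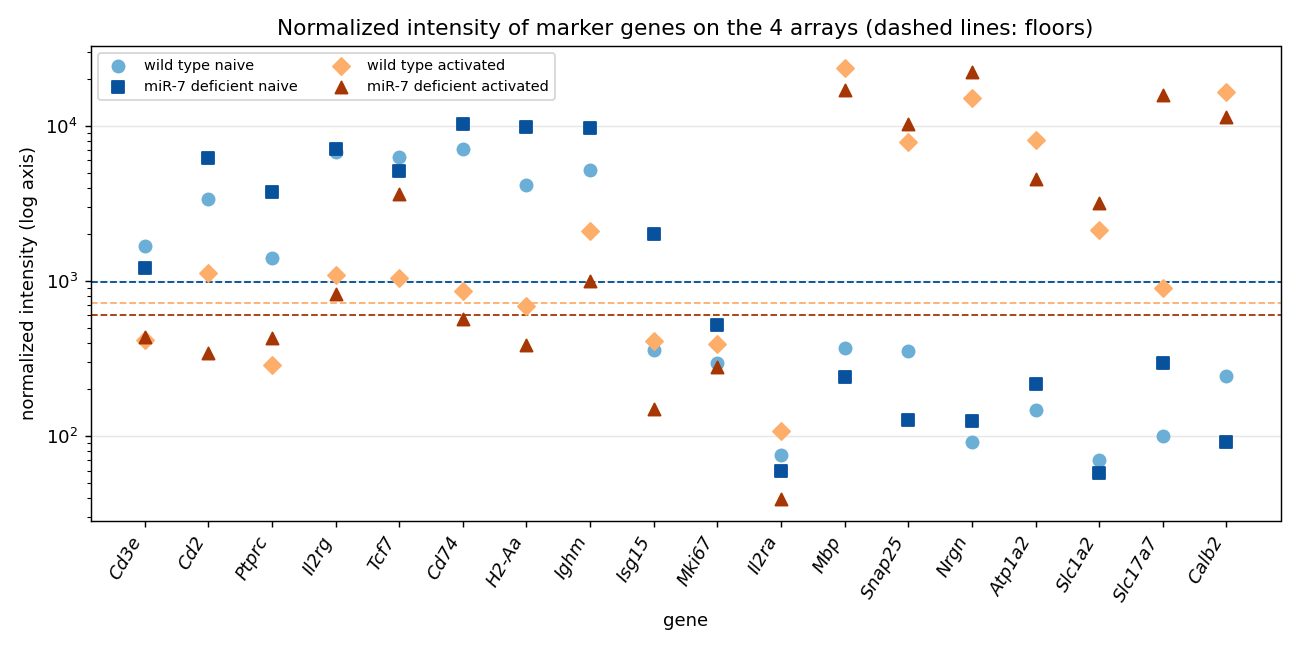
Normalized intensity (vertical log axis) of 18 marker genes (horizontal axis) on the 4 arrays, 1 symbol per array, with each array's floor as a dashed line in its colour. Lymphocyte genes such as Cd2 and Cd74 sit above the floor on both naive arrays, and Mbp, Snap25 and Nrgn sit above it on both arrays labelled activated and below it on both naive arrays.

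Between naive cells of both genotypes, interferon-stimulated genes stood out as higher in the miR-7 deficient array. Gbp2, an interferon-induced GTPase, had a log2 difference of 1.49 and Rtp4, another interferon-induced gene, one of 1.40. Isg15, the interferon-induced ubiquitin-like protein, read 1996 against 359, which lies below the floor, a difference of at least 1.02. Of 31 measured members of the interferon list 11 were above the floor, 5 of them 2-fold or more higher in the miR-7 deficient array, and their median of 0.94 lay at percentile 100 of random lists matched for intensity. As 8 of the 11 were above the floor on the miR-7 deficient array alone, their sign was fixed by the floor; without a floor 27 of the 31 were higher and 4 lower, with a median of 1.09.

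Other groups were higher too. Ribosomal protein genes had a median difference of 0.50 (percentile 100), with 73 of 75 members above 0, and Rps25 was highest at 1.28. Glycolysis and lactate transport genes had a median of 0.62 (percentile 99.8), with 12 of 12 members higher, among them Gpi1 (1.05) and the glucose transporter Slc2a1 (0.99). B cell markers had a median of 0.68 (percentile 99.9), with 7 of 8 members higher. They included the class II histocompatibility gene H2-Aa (1.24), Ighm (0.89), the heavy chain of immunoglobulin M, and the B cell receptor component Cd79b (0.74). Without a floor 13 of the 19 measured B cell markers were higher and 6 lower, with a median of 0.54. Activation-induced transcription factors had a median of 0.42 (percentile 97.8) over 6 members, 4 of them above the floor on the miR-7 deficient array alone; without a floor 16 of 21 were higher and 5 lower, and Myc, a regulator of growth, was furthest apart at 1.23 or more.

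Beside these groups, T cell receptor signalling genes had a median of 0.40 (percentile 94.1), with 14 of 17 members higher, and Ptprc, the leukocyte phosphatase CD45, differed by 1.41. Naive and quiescence genes had a median of 0.29 (percentile 83.1), myeloid and dendritic cell markers 0.35 (percentile 90.8), apoptosis regulators 0.31 (percentile 85.7) and immediate early and stress genes 0.29 (percentile 86.7). The MAP kinase pathway had a median of 0.22 (percentile 83.3), the PI3K, AKT and mTOR pathway 0.21 (percentile 78.5), ribosome biogenesis 0.13 (percentile 49.7), activation markers and costimulatory receptors 0.08 (percentile 52.2), cell cycle and DNA replication 0.02 (percentile 32.4) and reference genes 0.29 (percentile 83.1). Lists with under 5 members above the floor were not ranked. Among them, the published miR-7 targets had 3 members above the floor, Pik3cd (-0.02), Rps6kb1 (at least 0.01) and Psme3 (0.48).

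Across all genes above the floor of either naive array, 97 of 3457 were 2-fold apart, 70 higher and 27 lower in the miR-7 deficient array. Among the largest differences measured on both arrays were those of Dapl1 (1.79), a transcript of naive T cells, Cytip (1.57), a cytohesin-binding protein of leukocytes, Gbp2, Ptprc, Rtp4, H2-DMb1 (1.35), which loads class II molecules, Ly6a (1.33), Arap2 (1.30) and Rps25. Further interferon-induced genes were below the wild type floor, Tgtp1 at least 3.31-fold higher, Parp9 at least 3.25-fold and Igtp at least 2.98-fold, as were Ppp1r9b (2.86) and Slc4a9 (2.86). On the low side were Ammecr1l (-1.41), the heterochromatin protein Cbx3 (-1.40), Hoxd10 (-1.39), Nvl (-1.37), the peptidoglycan receptor Pglyrp1 (-1.24), Nectin4 (-1.23), Mindy4 (-1.21), Tef (-1.16), Mecom (-1.13) and Pigm (-1.04). Hoxd10 and Mecom, genes of restricted tissues, were above the floor on all 4 arrays, and whether their rows report these transcripts was not tested. Tpcn1, an endolysosomal ion channel, read 10568 in wild type and 478, below the floor, in the miR-7 deficient array, a difference of at least 10.7-fold, followed by Aldh1a2 (at least 4.09-fold), Kif9 (3.18), Pemt (2.65) and the metallothionein Mt1 (2.55).

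The split between higher and lower genes depended on scaling: 72.2% of the genes apart were higher in the main setting, 62.8% after centring, 39.3% after removing a trend on intensity and 30.2% when the pair was normalized alone, a setting added once the values were known. With the trend removed, activation-induced transcription factors (0.32, percentile 97.4) no longer lay outside the limits. Without a floor, 16.7% of all genes and 21.4% of the 618 background receptor genes were 2-fold apart.

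Between the arrays labelled activated, genes of the forebrain were higher in the miR-7 deficient array. Slc17a7, the vesicular glutamate transporter of cortical neurons, read 15853 against 902, a log2 difference of 4.13. Ttr, the thyroid hormone carrier made in choroid plexus and liver, differed by 3.10, and Rprm was at least 9.21-fold higher. Of 21 measured forebrain regional genes, in a list drawn up once the values were known, 19 were higher and 2 lower without a floor. The 10 above the floor, 7 of them on the miR-7 deficient array alone, had a median of 0.81 (percentile 100), for example Lhx2 (1.20) and Ppp1r1b (at least 1.75). Of these 10, 4 were not among the genes with the largest differences seen before the list was drawn up. The percentile is therefore no independent check. Over the 13 members not seen before, the median without a floor was 0.58. Hindbrain and cerebellar genes had a median of -0.23 (percentile 9.96).

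Among the lists fixed before the data were examined, myeloid and dendritic cell markers had a median of 0.50 (percentile 99.9) over 9 members, 5 of them above the floor on the miR-7 deficient array alone; without a floor 20 of 27 were higher and 7 lower, with a median of 0.37. Members were the complement genes C1qa (0.65) and C1qb (0.72), which microglia and macrophages express, and Sirpa (1.28). Ribosomal protein genes had a median of -0.21 (percentile 1.31), with 55 of 76 members lower, such as Rps27a (-0.75) and Rpl9 (-0.71). neuronal genes had a median of 0.14 (percentile 98.95), oligodendrocyte and myelin genes -0.24 (percentile 7.51) and astrocyte genes -0.07 (percentile 39.3), in lists drawn up once the values were known. Published miR-7 targets had a median of 0.10 (percentile 89.8) over 8 members, with 6 higher, 1 of them by 2-fold, and 2 lower, 0 of them by 2-fold. That median lay within the limits of random lists. A member above the floor on 1 array alone can take 1 sign only, so these counts do not describe the whole list. T cell receptor signalling (-0.16, percentile 14.9), naive and quiescence genes (0.13, percentile 89.6) and glycolysis (0.04, percentile 88.3) lay within the limits of random lists.

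In all, 263 of 5712 genes were 2-fold apart between these arrays, 127 higher and 136 lower. Besides Slc17a7 and Ttr, the highest were the prion protein gene Prnp (2.64), Mmp17 (2.43), Nptxr (2.41), Zbtb18 (2.17), Ddn (2.17), Ctxn1 (2.10), the neuronal calcium sensor Hpca (2.09) and Nell2 (1.99), and the bounds of Chrdl1, C1ql2, Cracdl and Rap1gap2 were 7.38-fold, 4.57-fold, 4.01-fold and 4.005-fold. Lower were the synaptic vesicle protein Vamp1 (-2.40), Tmem91 (-2.02), Fabp5 (-2.01), the prostaglandin D synthase Ptgds (-1.92), Prdx5 (-1.83), Resp18 (-1.74), Fnta (-1.73), Gad2 (-1.62), an enzyme of GABA synthesis, the granin Scg2 (-1.59) and Vtn (-1.57). Fzd1 (at least 2.93-fold), Tmem160 (2.92), Ank1 (2.72), Dst (2.70) and Nploc4 (2.63) were below the floor of the miR-7 deficient array. Neuronal genes without a floor (percentile 97.0) and ribosomal protein genes as the mean of all rows (-0.20, percentile 3.98) lay within the limits. Without a floor, 12.9% of all genes and 19.1% of background receptor genes were 2-fold apart.

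Between the array labelled activated and the naive array of wild type mice, genes of neurons and glia were higher and genes of lymphocytes were lower. Gabarapl1, an autophagy gene, differed by 4.73, Tubb4a, a tubulin of neurons and oligodendrocytes, by 4.06, and Stmn1, a regulator of microtubules, by 3.63. Mbp was at least 24.1-fold higher, Rtn1 23.7-fold, Stmn3 22.4-fold, App 21.8-fold and Sncb 20.8-fold. Cd74, the class II invariant chain, differed by -3.03, Il2rg, the shared interleukin receptor chain, by -2.63 and Tcf7, a transcription factor of naive T cells, by -2.59. The median difference over all genes was -0.17 here and -0.13 in miR-7 deficient cells, and the list values are placed against random lists that share that shift.

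The same contrast appeared list by list. Neuronal genes had a median of 2.08 in wild type and 2.06 in miR-7 deficient mice (percentile 100 in both) over 26 members, 25 and 26 of them above the floor on the array labelled activated alone; without a floor 28 of 30 were higher and 2 lower in each genotype, with medians of 3.98 and 4.39, for example Snap25, of synaptic vesicle fusion (at least 2.99 and 3.39). Oligodendrocyte and myelin genes had medians of 1.02 and 0.78 (percentile 100 in both), and without a floor 19 of 19 were higher in each genotype, with medians of 3.34 and 3.93. Astrocyte genes had medians of 0.72 (percentile 98.7) and 0.00 (percentile 43.7), with differences that leave no bound set to 0; over all 18 measured members without a floor their medians were 2.23 and 2.997. These 3 lists were drawn up once the values were known.

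T cell receptor signalling genes had medians of -0.81 and -1.48 (percentile 0 in both), and without a floor 28 and 27 of 31 members were lower, such as Lat (bounds of -2.33 and -2.73), the adaptor of T cell receptor signals, Cd3g (-2.23 and a bound of -2.77) and Cd2 (-1.58 and a bound of -3.36). Fyn, a kinase that neurons also express, was the member above the floor that was higher in both (0.33 and 0.05). Without a floor, the T cell receptor signalling genes above the naive floor had medians of -1.94 in wild type and -2.09 in miR-7 deficient mice. The floor of the array labelled activated was 721 in wild type and 606 in miR-7 deficient mice. Medians over bounds can therefore reach further down in miR-7 deficient mice. Naive and quiescence genes had medians of -1.06 and -1.47 (percentile 0 in both), with Satb1, a chromatin organizer, at a bound of -2.40 and at -3.002. B cell markers had medians of -1.60 and -3.28 (percentile 0 in both), and without a floor 18 and 17 of 19 members were lower.

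Genes that T cell activation is known to induce showed no general rise on the arrays labelled activated, and most lay below the floor. Of the cell cycle, activation marker and transcription factor lists together, 13 genes in wild type and 18 in miR-7 deficient mice were above it. Mki67, the proliferation marker, read 294 and 524 on the naive arrays and 391 and 280 on the arrays labelled activated, below every floor, and Il2ra, the interleukin 2 receptor alpha chain, read 75.3 and 59.9 against 108 and 39.2. Cell cycle and DNA replication genes had a median of -0.76 (percentile 4.82) in miR-7 deficient mice and -0.75 over 4 members in wild type, with Pcna, the replication clamp, at -0.86 and -1.17. Activation markers and costimulatory receptors had medians of -0.52 (percentile 11.7) and -0.95 (percentile 3.50) over 5 members each, and of 0.08 and -0.64 over all 18 without a floor, and the member furthest above 0 was Cd200 (at least 2.23 and 1.59), which neurons also express. Activation-induced transcription factors had a median of -0.02 over 4 members in wild type and of -1.11 (percentile 0.44) in miR-7 deficient mice, where Myc was lower by at least 1.93 on the log2 scale.

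Of the remaining lists fixed before the data were examined, glycolysis and lactate transport genes were higher with medians of 1.13 (percentile 99.9) and 0.42 (percentile 99.1), although Ldha, lactate dehydrogenase A, differed by -1.12 and -1.87. Reference genes had medians of 0.64 (percentile 99.7) and 0.17 (percentile 95.6), with Gapdh higher (1.13 and 0.85) and B2m, the class I light chain, lower (-1.42 and -1.90). Interferon-stimulated genes had a median of -1.45 (percentile 0) in miR-7 deficient mice and -0.80 over 4 members in wild type. Ribosomal protein genes had medians of -0.31 (percentile 30.7) and -0.95 (percentile 0.01), and ribosome biogenesis -0.29 (percentile 16.3) and -0.76 (percentile 2.46). Immediate early and stress genes had medians of -0.63 (percentile 2.89) and -1.07 (percentile 0.49), and apoptosis regulators -0.40 (percentile 2.17) and -0.57 (percentile 8.38). The MAP kinase pathway (0.36 and 0.00, percentiles 96.9 and 45.6), the PI3K, AKT and mTOR pathway (0.00 in both, percentiles 46.3 and 49.6), myeloid markers (0.00 and 0.01), cholesterol synthesis (0.12 and 0.00, percentiles 88.1 and 43.7) and published miR-7 targets (0.22 and 0.00, percentiles 71.1 and 43.1) lay within the limits of random lists.

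**Figure D2:**
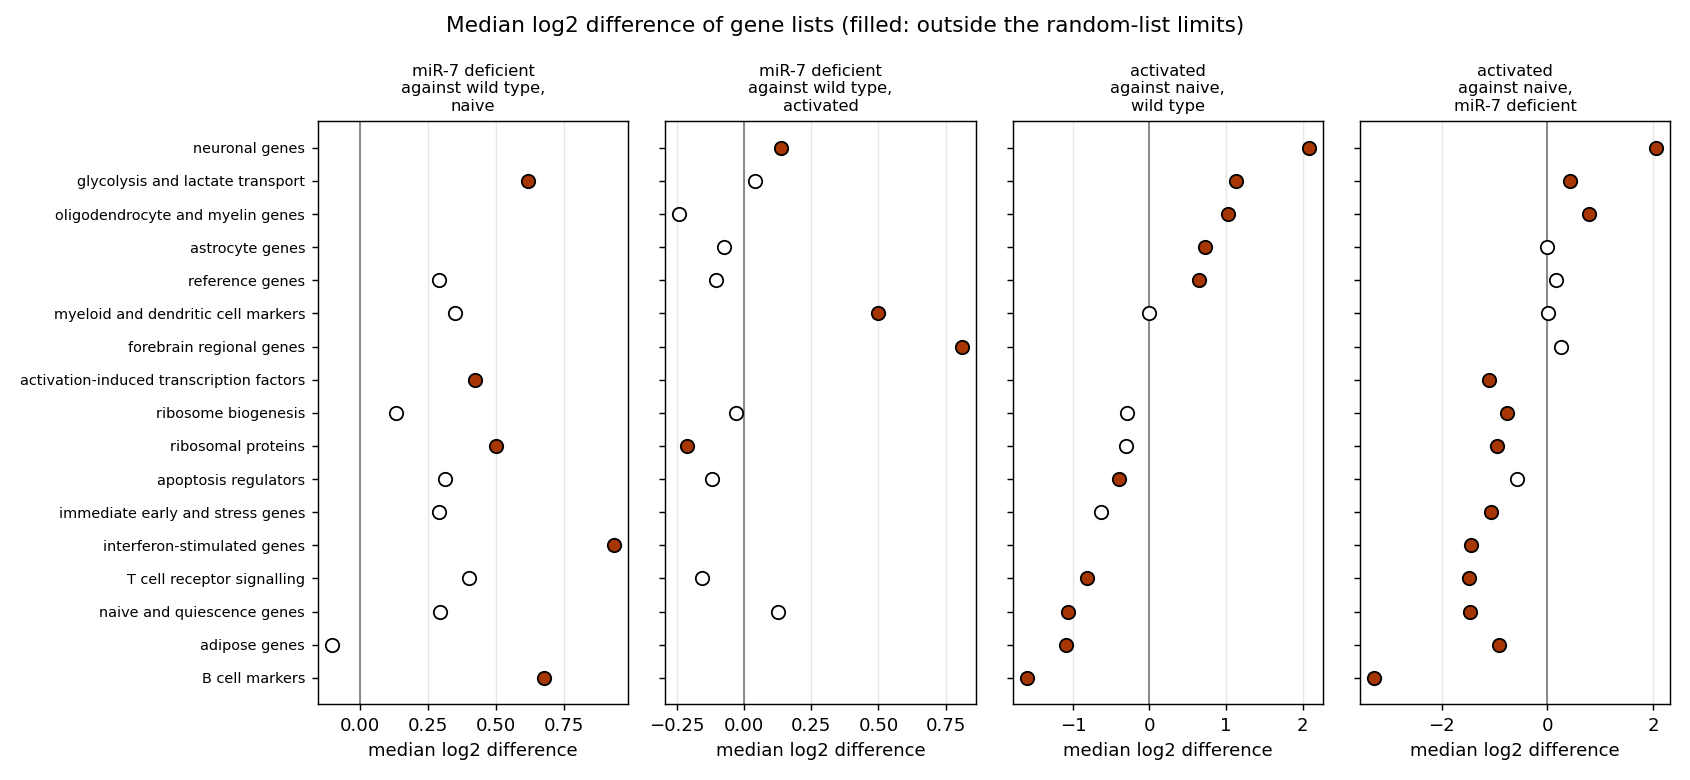
Median log2 difference (horizontal axis, with its own range in each panel) of the members above the floor, for each gene list (vertical axis) that lay outside the limits of random lists in at least 1 of the 4 comparisons. Filled points lie outside those limits, open points within them, and lists with under 5 members above the floor have no point; neuronal genes stand at 2.08 and 2.06 and B cell markers at -1.60 and -3.28 in the comparisons of the arrays labelled activated with the naive arrays.

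In wild type mice 1194 of 5127 genes were 2-fold apart between states, 743 higher and 451 lower in the array labelled activated. In miR-7 deficient mice the count was 1505 of 5817, 646 higher and 859 lower. Without a floor, 3788 genes were lower in wild type and 3756 in miR-7 deficient mice. Across 6233 genes the differences of both genotypes, which share no array, correlated at r = 0.80 and rho = 0.70. A total of 750 genes were 2-fold apart in both, all in the same direction, 498 higher and 252 lower, where independent lists would share 77.0 and 62.2. The genes are not independent replicates. In wild type mice the call of apoptosis regulators ended after centring (-0.23, percentile 2.87), with the trend removed (-0.45, percentile 8.905) and without a floor (-0.39, percentile 15.8), that of reference genes without a floor (0.48, percentile 97.0), and those of reference and astrocyte genes with the floor at the 99th percentile (0.00 in both). In miR-7 deficient mice the call of ribosome biogenesis ended with the trend removed (-0.49, percentile 3.745), as the mean of all rows (-0.61, percentile 8.73) and without a floor (-0.54, percentile 3.64), and that of glycolysis without a floor (0.03, percentile 83.9). After centring, 75.2% of the genes apart in wild type mice were higher in place of 62.2%, and in miR-7 deficient mice the majority turned from lower to higher, 52.1% in place of 42.9%.

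The named genes of the wild type comparison further included Tspan7 (4.39), the protease inhibitor Cst3 (3.90), Sparc (3.86), the noncoding RNA Norad (3.84), Calm2 (3.80), Tecr (3.73) and Cox5b (3.26) on the high side. On the low side were Klhl6 (-2.93), Gramd3 (-2.90), Gdpd3 (-2.84), the class I gene H2-D1 (-2.63), the lymphocyte diacylglycerol kinase Dgka (-2.48), the leukocyte actin bundler Lcp1 (-2.46) and Vim (-2.41). Lower by a bound were Tpcn1 (at least 14.7-fold), Ammecr1l (9.21), Cxcr4 (7.51), the chemokine receptor, H2-Aa (5.81) and Acp5 (5.74).

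In miR-7 deficient mice the highest were Tubb4a (4.49), Vamp2 (4.197) and Nsf (4.06), of synaptic vesicle fusion, Arf3 (3.89), Cst3 (3.88), Calm2 (3.68), Calm3 (3.55), Stmn1 (3.51), Norad (3.49) and Bex3 (3.48). Higher by a bound were Gabarapl1 (at least 36.2-fold), Dnm1 (32.3), Rtn1 (28.9) and Nrgn (22.6). The lowest were Gdpd3 (-4.0004), Gramd3 (-3.65), Dgka (-3.51), H2-Ab1 (-3.31), Il2rg (-3.09), H2-K1 (-3.04), Satb1, Cd53 (-2.99), H2-D1 (-2.93) and Klhl6 (-2.90), with bounds for Cd74 (17.0-fold), H2-Aa (16.3), Cxcr4 (12.5), Cd2 (10.3) and Samhd1 (10.2).

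The genotype difference of several lists was unlike between the naive arrays and the arrays labelled activated. Interferon-stimulated genes had a median difference of differences (labelled activated minus naive) of -0.75 (percentile 0), ribosomal protein genes -0.76 (percentile 0), B cell markers -0.74 (percentile 0.56) and T cell receptor signalling -0.40 (percentile 1.12), while myeloid markers stood at 0.26 (percentile 99.2). Apart from ribosomal protein genes, these values largely restate the difference of 1 state, because most members lay below both floors of the other: on the arrays labelled activated 3 interferon-stimulated, 3 B cell and 8 T cell receptor signalling genes were above a floor, and on the naive arrays 6 myeloid markers. Of 6233 genes 600 were 2-fold apart, 214 higher and 386 lower. The genotype differences of the naive arrays and the arrays labelled activated correlated at r = -0.06 and rho = -0.09 across genes, and 3 genes were 2-fold apart in both, where independent lists would share 1.43 higher and 0.59 lower. Genes below both floors of a pair were set to 0 there, and no pair was replicated. A correlation near 0 therefore does not show that the genotype acts differently between states.

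The genes with the highest difference of differences were Ddn (2.28), Nvl (1.99), Tef (1.85), Myh7b (1.80), Trpm1 (1.79), Hoxd10 (1.76), Svs1 (1.76), Nectin4 (1.74), Mecom (1.73) and Defb9 (1.69). Whether the rows of Trpm1, Hoxd10, Svs1, Mecom and Defb9, genes of restricted tissues, report these transcripts was not tested. The lowest were Prdx5 (-2.08), a peroxiredoxin, Odc1 (-2.05), the first enzyme of polyamine synthesis, Fnta (-2.03), Fis1 (-1.82), Slc2a1 (-1.79), Pgk1 (-1.71), a glycolytic kinase, Mrpl24 (-1.69), Fbl (-1.65), Hmgn1 (-1.64) and Cmah (-1.63). With the trend on intensity removed, 58.1% of the genes apart were higher, in place of 35.7%, and T cell receptor signalling (-0.26, percentile 2.80) no longer lay outside the limits. Without a floor myeloid markers (0.18, percentile 84.4) lay within them.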

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

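All tests in this part were chosen after the results were seen, and no difference between states was tested, with 1 array per group. Bootstrap intervals resampled the genes of a list 10000 times on the same arrays. They hold no variation between arrays or animals, and the genes are not independent replicates.

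The genotype difference of ribosomal protein genes ran in opposite directions in the 2 states, with medians of 0.50 on the naive arrays and -0.21 on the arrays labelled activated, and a median difference of differences of -0.76. Among the genes named for the difference of differences, 7 were apart in opposite directions by more than 2 times the SD between rows of a gene. These genes were named for a large difference of differences, a choice that favours opposite directions, and that SD is no replicate error. Odc1 differed by 1.23 and -0.82 (difference -2.05), Fis1, of mitochondrial fission, by 0.85 and -0.96 (-1.82), Slc2a1 by 0.99 and -0.80 (-1.79) and Pgk1 by 0.91 and -0.80 (-1.71). In the other direction Trpm1 differed by -0.83 and 0.96 (1.79), Svs1 by -0.95 and 0.80 (1.76) and Defb9 by -0.74 and 0.95 (1.69). These differences between states were not tested.

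The first pattern weighed is the presence of nervous system transcripts, with few T cell transcripts, on both arrays labelled activated. Activated T cells alone are argued against by 51 neuronal, oligodendrocyte and astrocyte genes not seen among the extremes, with medians of 2.39 in wild type (bootstrap 95% interval 1.97 to 3.51) and 3.14 in miR-7 deficient mice (2.05 to 3.70), while their own cell cycle, activation and transcription factor genes decide nothing, with medians of -0.52 (13 genes, -0.86 to 0.00) and -0.86 (18 genes, -1.14 to -0.07). A minor share of nervous system RNA in T cell RNA is left open at the limit first set, -2. The T cell receptor signalling genes above the naive floor had medians of -1.94 (15 genes, -2.29 to -1.66) and -2.09 (16 genes, -3.14 to -1.56). At a limit of -1, named beside it, both intervals lay under the limit. Those genes were chosen for being above the naive floor, which favours lower values on the other arrays. Whether activation itself lowers them was not tested, so the limit of -1 decides nothing here. Nervous system RNA in place of T cell RNA, for example through exchanged samples or value columns, had the values it needs. Astrocyte genes not seen among the extremes had medians of 2.17 (bootstrap 95% interval 0.14 to 3.71) and 2.99 (0.69 to 3.48). The highest of the liver, skeletal muscle, kidney, testis and adipose lists reached -0.32. An added share of nervous system RNA would give the same order, so these values do not tell replacement from an added share. The labels name splenocytes and a bead isolation of CD4+ cells, and so no source of brain cells. Whether the arrays hold no T cell RNA or a part of it stays open.

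The second pattern is the higher signal of interferon-stimulated genes on the miR-7 deficient naive array. With the trend on intensity removed the median was 0.87 at percentile 100. This cannot exclude a difference that depends on intensity, because the floor fixed the sign of 8 of the 11 members in the main setting. A larger share of B cells could raise no gene by more than genes that B cells alone express. The B cell list also holds class II genes (H2-Aa, H2-Ab1, H2-Eb1 and Cd74), which other cells express, so its median is no strict limit. The interferon median exceeded the B cell median by 0.26, with a bootstrap 95% interval of -0.41 to 0.90. Most of the 11 interferon values are lower bounds, so the difference may be larger than 0.26. B cells, which a CD4 selection should remove, cannot be told apart from a change in T cells with 11 and 8 genes. The genotype, an infection or the handling of 1 animal stay open as untested explanations.

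The third pattern is the higher signal of forebrain genes on the miR-7 deficient array labelled activated. An intensity effect stays open: with the trend on intensity removed the 13 forebrain genes not seen among the extremes had a measured median of 0.61 (0.29 to 1.27), against 0.58 before, but 4 of them were above the floor, too few to rank. A larger share of neurons stays open: among genes not seen among the extremes the forebrain median exceeded the neuronal one by 0.49 (0.01 to 1.37), but the 4 above the floor gave an interval of -0.12 to 1.84. If the arrays hold nervous tissue, another brain region is a candidate explanation: forebrain genes not seen among the extremes exceeded hindbrain and cerebellar genes by 0.59 (0.13 to 1.49, measured values of 13 and 18 genes). The genotype stays open and untested.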

How the results depend on the processing

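The floor at the 75th percentile and the normalization of a pair alone were chosen after the results were seen; the other alternatives were planned. The majority direction of the genes apart turned in several settings. In the naive comparison 72.2% were higher, against 49.4% without a floor, 39.3% with the trend removed and 30.2% with the pair normalized alone. For the difference of differences 35.7% were higher, against 58.1% with the trend removed. Between states in miR-7 deficient mice 42.9% were higher, against 52.1% after centring (744 higher, 685 lower) and 52.4% with the trend removed (739 and 670). The genotype comparison of the arrays labelled activated was near an even split at 48.3%. Its settings ranged from 40.0% with the mean of all rows to 55.8% with the trend removed. The majority also turned without a floor (51.9%), with the floor at the 99th percentile (54.8%) and with the pair normalized alone (51.7%). No correlation changed sign, and the correlation of the genotype differences stayed between -0.11 and -0.02. Among 900 results for named genes 817 kept their call and 83 lost it, and among 586 list results 525 kept theirs, 27 lost and 34 gained one. Counts are given below as total, higher and lower. A lower floor keeps more genes and a higher one fewer by construction; for the other settings the cause was not tested. A comparison from unnormalized intensities and a count of miR-7 seed sites were not run.

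Without a floor the counts were 3471, 1715 and 1756 for the naive genotype comparison, 2684, 1394 and 1290 for that of the arrays labelled activated, 7611, 3823 and 3788 between states in wild type, 7204, 3448 and 3756 in miR-7 deficient mice, and 6342, 3126 and 3216 for the difference of differences. The lists outside the limits were then 8 in the naive comparison and 13 between states in wild type, and the activation differences of both genotypes correlated at 0.68.

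With the floor at the 99th percentile the counts were 18, 10 and 8 (naive), 104, 57 and 47 (labelled activated), 462, 248 and 214 (states, wild type), 719, 296 and 423 (states, miR-7 deficient) and 225, 88 and 137 (difference of differences). The lists outside the limits were 3 in the naive comparison, 3 and 5 between states in wild type and miR-7 deficient mice, and 2 for the difference of differences.

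With the floor at the 75th percentile the counts were 724, 391 and 333 (naive), 909, 452 and 457 (labelled activated), 3643, 1992 and 1651 (states, wild type), 3925, 1889 and 2036 (states, miR-7 deficient) and 2273, 986 and 1287 (difference of differences), with 8 lists outside the limits in the naive comparison and 4 in that of the arrays labelled activated.

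With the mean of all rows of a gene the naive counts were 49, 38 and 11, and for the arrays labelled activated the total was 160 with 64 higher and 1 list outside the limits. Between states the wild type total was 793 with 281 lower, and 421 genes were higher in miR-7 deficient mice. The difference of differences gave 356, 101 and 255.

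With the trend on intensity removed 35 genes were higher and 54 lower in the naive comparison, and 218 lower for the difference of differences. With the pair normalized alone 29 were higher and 67 lower in the naive comparison. After centring 294 genes were lower between states in wild type.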

Other observations

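Genes known from cell types other than T cells were also above the floor on at least 1 naive array. Whether their rows report such cells was not tested. On the wild type and miR-7 deficient naive arrays the invariant chain gene Cd74 read 7065 and 10307, the alpha globin gene Hba-a1 2556 and 1844, the neutrophil gene Lcn2 2961 and 3912, the natural killer receptor Ncr1 1493 and 687 (below the floor), and the adipocyte fatty acid carrier Fabp4 3240 and 3529. S100a9, a neutrophil calcium-binding protein, read 804 (below the floor) and 2563. Foxp3, the regulatory T cell factor and so no marker of another cell type, read 1385 and 763 (below the floor). Of the 14 measured CD8 T and NK cell markers 3 were above a naive floor. Among these the chemokine gene Ccl5, which other T cells also make, read 2988 and 5794. Adipose genes had a median genotype difference of -0.10 (percentile 14.2) in naive cells and medians of -1.09 (percentile 0.30) and -0.91 (percentile 0.95) on the arrays labelled activated against naive.

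Lists of helper T cell subsets held few members above the floor. In the naive comparison they included Ccl5 (0.96) of the Th1 genes, Il4ra (a bound of -0.23) of the Th2 genes and Rora (-0.27) of the Th17 genes. Follicular helper genes had 0 members above the floor, and the 3 regulatory T cell genes above it had a median of 0.08. Of the cytokines and chemokines, Ltb, a lymphotoxin subunit, differed by 0.12 and Lif by -0.29. Ltb was lower on the arrays labelled activated (bounds of -2.44 and -2.81). Genes of miRNA processing and silencing had medians of 0.00 (percentile 58.3) between the arrays labelled activated and -0.14 over 4 members in naive cells, with Tnrc6a, a silencing scaffold, at 0.11 in naive cells and -0.97 between the arrays labelled activated. Erythroid and platelet markers had a median of -1.13 over 4 members between the arrays labelled activated, with Hba-a1 at a bound of -1.16.

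Transcripts of organs other than brain were scarce on the arrays labelled activated. Of the liver genes, Ttr and Ass1 were above a floor, and over all 13 measured members without a floor the medians, labelled activated against naive, were -0.59 and -0.52 in wild type and miR-7 deficient mice. The corresponding medians were -0.40 and -0.32 for skeletal muscle, -0.37 and -0.70 for kidney and -0.61 and -0.66 for testis genes. Of the choroid plexus genes, Ttr read 2541 in wild type and 21858 in miR-7 deficient mice and Enpp2 read 1400 and 1297. Calb2, a calcium-binding protein of neurons on the hindbrain and cerebellar list, read 16516 and 11462.

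Several genes of restricted tissues gave high intensities on all 4 arrays. Mecom read between 4938 and 10836, Defb9, a defensin of the male tract, between 3129 and 10177, Hoxd10 between 2172 and 5933 and Aqp4, the astrocyte water channel, between 1316 and 3458. Aqp4 was higher on the naive arrays, against the direction of most astrocyte genes. Whether such rows report these transcripts was not tested.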
